A study of Mus musculus with 20 samples.

How the data were processed

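Gene expression was measured on 20 Affymetrix whole-transcript microarrays in mouse embryonic fibroblasts of the ICR strain. Per the labels, the cells were infected with pMX retroviruses for GFP, Oct4, Jhdm1b, Oct4+Jhdm1b or Oct4+Jhdm1b(jmjc) and cultured with or without vitamin C. This gave 10 groups of 2 arrays each. Per the labels' protocols, the medium was changed daily, the cells were detached with trypsin, feeder cells were removed, total RNA was extracted with Trizol, and biotin-labelled cDNA was made. The dose and duration of vitamin C, the time of harvest, the change behind the name jmjc, and the array's annotation build were not given in the sources used here. The labels do not say that the 2 arrays of a group came from separate cultures, so the p-values may measure only technical spread.

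The deposited values were RMA summaries per probe set on a log2 scale. The submitters' processing notes name RMA and Partek, without versions or settings. The table held 28853 probe sets with values from 0.68 to 13.9 log2 and 0 missing values. The unit log2 was read from the range of the values together with the naming of RMA. All 20 columns were mapped to a sample by the labels.

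Each probe set took the gene symbol of the deposited platform table, where 21789 probe sets had 1 symbol, 1621 had several and 5443 had none. Of the probe sets with 1 symbol, 21698 matched a mouse gene table, which was used only to check names. Probe sets with several symbols, or with none, were not used for genes. For each of 999 genes with more than 1 such probe set, the probe set with the highest mean over the 20 arrays was kept, which left 19938 genes. No gene was removed for a low value.

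Linear models were fitted with limma 3.58.1 in R 4.3.3, with 10 group means over all 20 arrays and moderated standard errors from eBayes. The fit had 10 residual degrees of freedom and a prior of 5.82. The spread of each gene was pooled over all groups, so a group with a wide spread also widened the SE of comparisons without it. Comparisons were vitamin C with against without in each infection and averaged over the 5 infections, Jhdm1b against GFP, Oct4 against GFP, Oct4+Jhdm1b against Oct4, Oct4+Jhdm1b against Oct4+Jhdm1b(jmjc), and Oct4+Jhdm1b(jmjc) against Oct4. Each of the virus comparisons was made in both vitamin C states. A set of 3 interactions asked whether a vitamin C effect differed between infections. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The number of arrays limits the precision. The median distance from an estimate to either end of its 95% confidence interval was 0.16 log2 for the average vitamin C effect, 0.35 for comparisons of a pair of groups, and 0.50 for interactions.

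Groups of genes came from 26 fixed lists. The lists were CDK inhibitors, p53 targets, mitosis, DNA replication, ribosome biogenesis, pluripotency, hairpins of the miR-302 cluster, mesendoderm and primitive endoderm, epithelial genes, mesenchymal genes, collagens, collagen-modifying enzymes, hypoxia and glycolysis, NRF2 targets, interferon response, senescence-associated secretory genes, cholesterol synthesis, germline genes, JmjC demethylases and TET, Hox genes, and markers of macrophages, endothelium, muscle, neural and glial cells, adipocytes and skeletal tissue. Lists were tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 26 lists. For each list the number of genes past the threshold was also counted after adjustment over the list alone.

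The comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule Pou5f1 and Kdm2b are given in every group. For the average vitamin C effect, and for Jhdm1b against GFP, Oct4 against GFP, Oct4+Jhdm1b against Oct4 and Oct4+Jhdm1b against Oct4+Jhdm1b(jmjc) with vitamin C, up to 10 genes with the highest and 10 with the lowest log2 change are named. They had to pass the threshold and have groups that did not overlap, or, for the average, the same sign in all 5 infections. The rule names up to 3 genes in each direction in the other comparisons, up to 5 in each direction in an interaction, and up to 4 members of each list, those past the threshold first.

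The fit was tested on simulated data with 19938 genes, of which 200 were changed by a known amount. For the average vitamin C effect 96.2% of changes of 0.5 log2 were recovered and 100% of changes of 1 log2. For Jhdm1b against GFP with vitamin C the recovered shares were 16.2% at 0.5 log2, 85% at 1 log2 and 100% at 2 log2. For Oct4+Jhdm1b against Oct4 with vitamin C they were 10%, 88.8% and 100% at the same sizes. For the interaction of vitamin C and Jhdm1b they were 1.25%, 36.2% and 97.5%. Calls among unchanged genes numbered 14, 9, 9 and 2 in these comparisons. A single list of the 26 shifted by 0.3 log2 in Jhdm1b against GFP gave an adjusted p of 1.73e-14 with the preset correlation and 9.33e-05 with an estimated correlation, and 0 other lists were called. The simulated genes were drawn independently, so this says nothing about false calls of lists whose members are correlated. The recovered shares hold for 200 changed genes, and with fewer the adjusted threshold would be harder to reach.

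Alternatives were a variance prior with trend and robust fitting, array quality weights, arrays centred on their medians, repeated quantile normalization, genes at or above the median mean level, fits of the compared groups alone, all probe sets in place of genes, an added fold threshold, a block for the replicate number, and leaving out each array in turn. No scan date or batch was given in the labels, so batches could not be examined. Pictures were drawn with matplotlib 3.10.9.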

Results

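Expression was profiled in mouse embryonic fibroblasts carrying 1 of 5 retroviral infections, each grown with or without vitamin C, with 2 arrays in each of the 10 groups. The viruses delivered GFP as a control, Oct4 (gene Pou5f1, a transcription factor of pluripotent cells), Jhdm1b (gene Kdm2b, a histone demethylase of the JmjC family), both together, or Oct4 with Jhdm1b(jmjc), whose change was not given in the sources used here. Array medians lay between 4.91 and 5.03 log2, and across genes the 2 arrays of a group correlated at Pearson's r from 0.988 to 0.993. The first principal component held 30.7% of the variance and separated arrays with Oct4 virus from those without. The second held 12.4% and separated arrays with vitamin C from those without. On the first component the Oct4+Jhdm1b(jmjc) arrays numbered 2 lay at -9.83 and -5.37, below the arrays numbered 1 at 15.2 and 13.4.

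The delivered genes were high in the infections named for them. Pou5f1 was 3.76 ± 0.00 log2 (SD, n = 2) in GFP with vitamin C, 3.49 ± 0.47 without it, and 3.58 ± 0.26 and 3.85 ± 0.26 in Jhdm1b with and without vitamin C. These levels were taken as its background, although background was not measured. It was 12.26 ± 0.24 and 12.22 ± 0.29 in Oct4, 11.61 ± 0.37 and 11.81 ± 0.27 in Oct4+Jhdm1b, and 10.96 ± 1.20 and 11.16 ± 0.92 in Oct4+Jhdm1b(jmjc), each with and without vitamin C. In the last infection the Pou5f1 values were 11.81 and 10.11 with vitamin C and 11.81 and 10.52 without it, the lower one in each case on the array numbered 2. Kdm2b was 5.82 ± 0.33 and 5.87 ± 0.17 in GFP and 6.0 ± 0.21 and 5.91 ± 0.05 in Oct4. It was 10.36 ± 0.12 and 10.40 ± 0.00 in Jhdm1b, 9.57 ± 0.03 and 9.77 ± 0.06 in Oct4+Jhdm1b, and 9.46 ± 0.14 and 9.71 ± 0.48 in Oct4+Jhdm1b(jmjc), in the same order. The probe sets do not separate viral from endogenous transcripts.

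**Figure D1:**
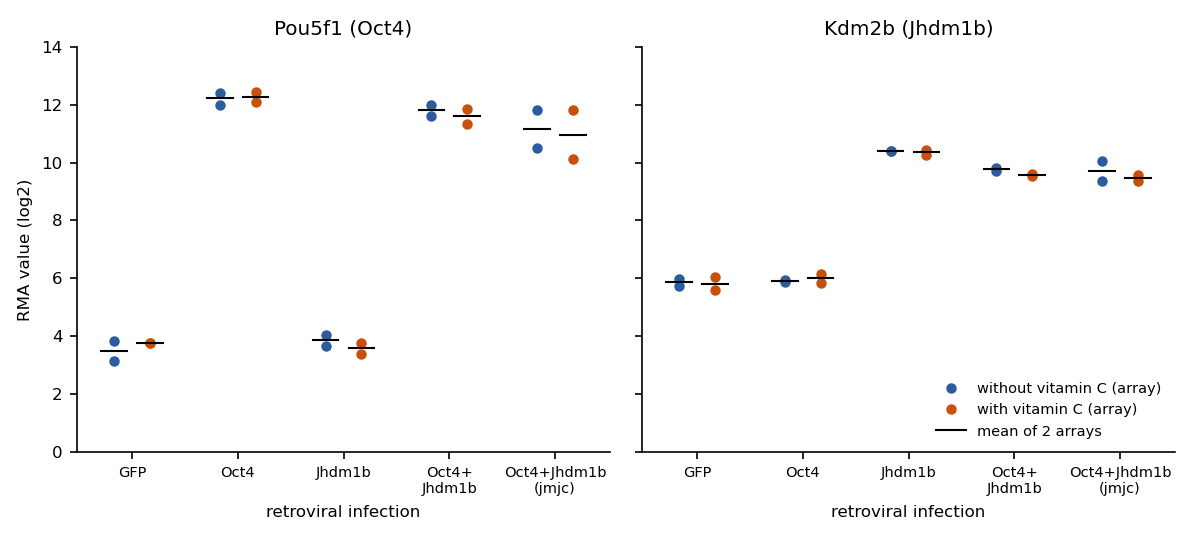
RMA values (log2) of Pou5f1 and Kdm2b by retroviral infection, with each point an array and each line the mean of 2 arrays, in blue without and in orange with vitamin C. The Oct4+Jhdm1b(jmjc) arrays numbered 2 have Pou5f1 at 10.11 and 10.52, below 11.81 on the arrays numbered 1.

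On average over the infections, cell division genes were higher and a number of amino acid stress genes lower with vitamin C. The average effect over the 5 infections asked what vitamin C did whatever virus the cells carried. Lum, for an extracellular matrix proteoglycan, rose by 1.71 ± 0.20 log2 (SE, 10 arrays in each state, adjusted p = 3.12e-05), a 3.26-fold increase. Glipr1 rose 2.65-fold (adjusted p = 7.85e-08) and As3mt, for an arsenic methyltransferase, rose by 1.31 ± 0.06 (adjusted p = 9.41e-09). Penk rose by 1.14 ± 0.17, the chemokine gene Cxcl5 by 1.12 ± 0.08, the water channel gene Aqp1 by 1.10 ± 0.08 and Sncg by 1.07 ± 0.09. The mitotic motor gene Kif11 (adjusted p = 4.92e-07), Parpbp and Hpgd, the last by 1.03 ± 0.21, completed the 10 highest. Aldh1l2, for a mitochondrial folate enzyme, fell by 1.46 ± 0.11 (adjusted p = 4.26e-07). Trib3, Asns and Ddit3, targets of the stress factor ATF4, changed by -1.40 ± 0.08 (adjusted p = 7.85e-08), -1.17 ± 0.08 and -1.11 ± 0.06. Further low values were Cth at -1.05 ± 0.09, the amino acid transporter genes Slc7a11 at -1.03 ± 0.08 and Slc7a3 at -1.01 ± 0.08, Inhba at -1.01 ± 0.09, the lactate transporter gene Slc16a3 at -0.95 ± 0.07 and Rgs16 at -0.94 ± 0.07. By the naming rule each of these 20 genes had the same sign in all 5 infections. Trib3 ranged from -0.84 to -1.77 and Lum from 0.80 to 2.64 among infections.

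In limma's test with Benjamini-Hochberg adjustment 1989 of 19938 genes passed for the average effect, 1076 higher and 913 lower, and 1693 of these had the same sign in all 5 infections. At least a change of 1 log2 was reached by 21 genes. At an unadjusted p under 0.05 there were 4452 genes, with 996.9 expected by chance. Of the 1989 genes, between 95.7% and 98.1% had the sign of the average in a given infection, although each infection is itself part of that average. Across genes, which are not independent replicates, the effects in pairs of infections correlated at Pearson's r from 0.196 to 0.457. Leaving out any 1 of the 20 arrays gave between 1669 and 2063 genes.

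**Figure D2:**
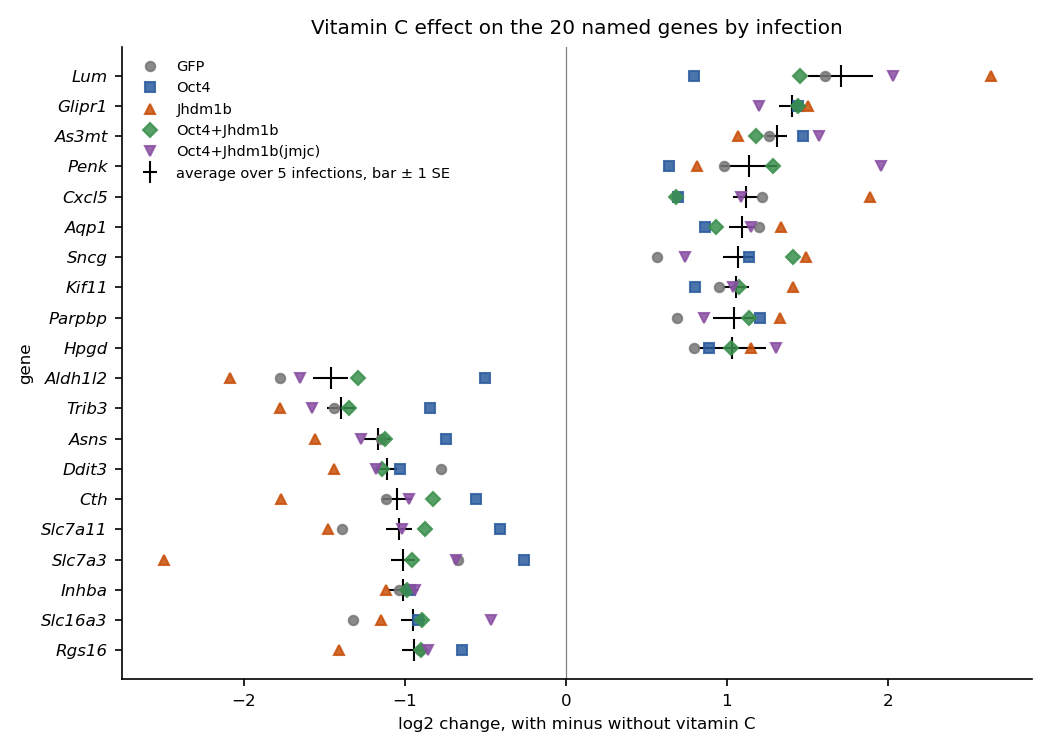
Log2 change with minus without vitamin C (horizontal axis) for the 20 named genes (vertical axis), with coloured points for the 5 infections and a black bar for the average ± 1 SE. By the naming rule all points of the 10 higher genes lie above 0 and all points of the 10 lower genes lie below 0. Slc7a3 reaches -2.50 in Jhdm1b.

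Genes of the cell cycle rose as whole lists under vitamin C. All 29 measured mitosis genes rose, and 29 passed adjusted over the list alone, with a median of 0.76 log2 (camera adjusted p = 1.6e-58; adjusted p = 0.00218 with an estimated correlation); examples were Kif11, Kif2c at 1.01 ± 0.07, Bub1b at 0.94 ± 0.06 and Ccnb2 at 0.92 ± 0.07. DNA replication genes rose in 27 of 30, and in 30 adjusted over the list alone, with a median of 0.52 (adjusted p = 5.87e-39; adjusted p = 0.00545 with an estimated correlation), including Prim1 at 0.85 ± 0.09 and Tk1 at 0.83 ± 0.07. Cholesterol synthesis genes rose in 16 of 19, and in 19 adjusted over the list alone, with a median of 0.34 (adjusted p = 6.01e-20; adjusted p = 0.00545 with an estimated correlation), including Insig1 at 0.60 ± 0.08 and Idi1 at 0.59 ± 0.08. Of 6 measured CDK inhibitors 3 rose, Cdkn2c by 0.55 ± 0.09, Cdkn1b by 0.31 ± 0.08 and Cdkn1c by 0.25 ± 0.06, and 4 passed adjusted over the list alone (adjusted p = 0.00155; adjusted p = 0.0427 with an estimated correlation). Cdkn2a at -0.02 ± 0.09 (adjusted p = 0.944) and Cdkn2b at 0.15 ± 0.08 (adjusted p = 0.27) did not pass over all genes. Cdkn1a, also on this list, had no probe set with a single gene symbol, so nothing can be said about it.

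Hypoxia and p53 lists moved the other way. Hypoxia and glycolysis genes fell in 11 of 27, and in 14 adjusted over the list alone, with a median of -0.18 (adjusted p = 4.71e-10; adjusted p = 0.00224 with an estimated correlation). They included Slc16a3, P4ha1 at -0.77 ± 0.06, Ero1a at -0.74 ± 0.11 and Bnip3 at -0.60 ± 0.07. Of 22 p53 targets 7 fell, and 13 adjusted over the list alone, with a median of -0.21 (adjusted p = 1.5e-07; adjusted p = 0.00659 with an estimated correlation). Pmaip1 was at -0.72 ± 0.07, Sesn2 at -0.59 ± 0.07, Plk2 at -0.54 ± 0.09 and Mdm2 at -0.52 ± 0.06. Cdkn1a, Bax and Gdf15 of the p53 list had no probe set with a single gene symbol and were left out. Collagens rose in 5 of 19, and in 6 adjusted over the list alone, among them Col6a3 at 0.56 ± 0.07 and Col3a1 at 0.45 ± 0.12 (adjusted p = 0.00272), a call lost at adjusted p = 0.567 with an estimated correlation. Interferon response genes rose in 6 of 25, and in 7 adjusted over the list alone, such as Oasl2 at 0.58 ± 0.12 (adjusted p = 0.00968), a call lost at adjusted p = 0.681 with an estimated correlation. This call was also lost, at adjusted p = 0.159, without the Oct4+Jhdm1b(jmjc) array numbered 2 without vitamin C. The interferon average covered opposite directions: the medians were 0.34 in GFP, 0.17 in Jhdm1b and 0.13 in Oct4+Jhdm1b(jmjc), but -0.20 in Oct4 and -0.18 in Oct4+Jhdm1b. In GFP 24 of 25 interferon genes lay above 0 (adjusted p = 6.39e-12; adjusted p = 0.15 with an estimated correlation), and in Oct4 20 of 25 lay below 0 (adjusted p = 0.00258; adjusted p = 0.664 with an estimated correlation). This difference between GFP and Oct4 was not tested. The Oct4 call was lost at adjusted p = 0.222 without its array numbered 1 with vitamin C, and its median was -0.31 without the array numbered 1 without vitamin C. The interferon median was 0.33 in Jhdm1b without the array numbered 1 with vitamin C. In Oct4+Jhdm1b(jmjc) it was -0.06 without the array numbered 2 without vitamin C and 0.43 without the array numbered 1 of that group. With camera 8 of the 26 lists passed, and 6 of them also with an estimated correlation.

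The remaining lists did not pass camera for the average effect, though single members did. Among collagen-modifying enzymes 3 of 15 fell, P4ha1, P4ha2 at -0.50 and Plod2 at -0.35, while Loxl3 rose by 0.25 (adjusted p = 0.271 for the list). Senescence-associated secretory genes fell in 6 of 25, such as Ptgs2 at -0.63 and Mmp3 at -0.53, while Cxcl5 rose (adjusted p = 0.446). NRF2 targets rose in 5 of 22, such as Gstm1 at 0.43, and fell in 3, such as Slc7a11 and Hmox1 at -0.65; their median of 0.06 and mean of -0.01 differed in sign (adjusted p = 0.442). Mesenchymal genes rose in 3 of 20, such as S100a4 at 0.48, and fell in 3, such as Fn1 at -0.29 (adjusted p = 0.961). Epithelial genes fell in 3 of 25, Krt19 at -0.39, Dsp at -0.30 and Cdh1 at -0.20 (adjusted p = 0.442). Among mesendoderm and primitive endoderm genes Eomes fell by 0.37 and Dab2 rose by 0.29 of 19 measured (adjusted p = 0.56). Pluripotency genes fell in 2 of 30, Trim71 and Tbx3, both at -0.19 (adjusted p = 0.367), and in 0 adjusted over the list alone. The JmjC demethylases and TET list had 1 of 21 lower, Kdm5b at -0.26 ± 0.06 (adjusted p = 0.334), and the germline list 2 of 20 higher, Rpl10l and Slc25a31 (adjusted p = 0.554). None of 5 hairpins of the miR-302 cluster (adjusted p = 0.634), 22 ribosome biogenesis genes (adjusted p = 0.995), 37 Hox genes (adjusted p = 0.961) or 22 muscle markers (adjusted p = 0.377) passed limma's test. Of the other markers, Kdr and Egfl7 fell among 12 for endothelium (adjusted p = 0.194), Lyz2 rose among 16 for macrophages (adjusted p = 0.995), Ncam1 fell among 15 for neural and glial cells (adjusted p = 0.961), Cebpa rose while Plin1 and Dgat2 fell among 13 for adipocytes (adjusted p = 0.92), and Alpl rose among 9 for skeletal tissue (adjusted p = 0.15). The median and the mean also differed in sign for the germline list, at -0.003 and 0.016. For the ribosome biogenesis, Hox and macrophage lists both were negative, with medians of -0.024, -0.028 and -0.025, while the direction given by camera was up.

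**Figure D3:**
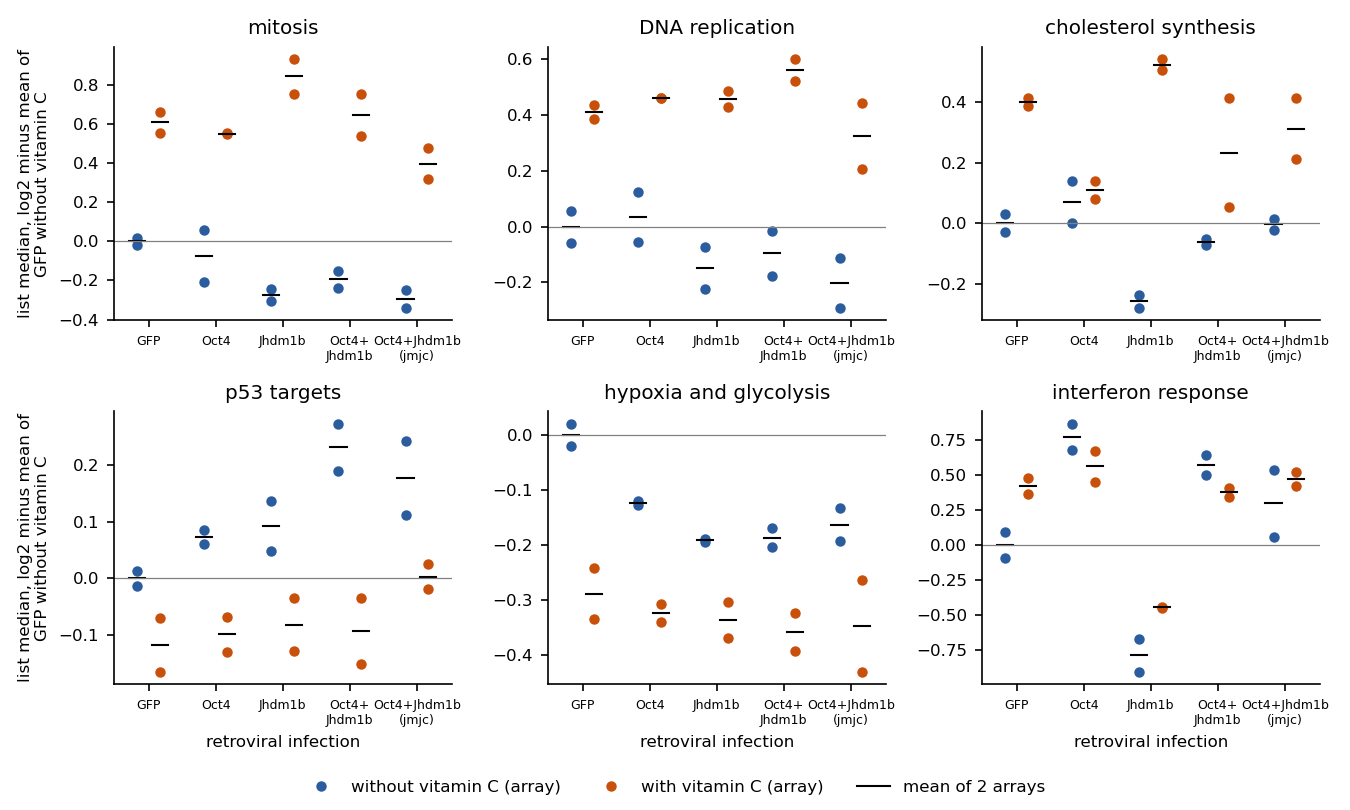
Median of 6 gene lists in each array, as log2 minus the mean of GFP without vitamin C, by retroviral infection; points are arrays, lines are means of 2 arrays, blue is without and orange with vitamin C. In every infection both arrays with vitamin C lie above both arrays without it for mitosis and DNA replication and below them for p53 targets and hypoxia and glycolysis, and the Jhdm1b arrays have interferon medians from -0.91 to -0.44.

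Among genes past the threshold whose groups did not overlap, As3mt was 1 of the 3 highest in each infection but Jhdm1b, and Trib3 1 of the 3 lowest in each but Oct4. In GFP, Glipr1 rose by 1.44 ± 0.19 (n = 2 against 2, limma adjusted p = 0.00314), and Ppbp and As3mt also rose, while Aldh1l2, Trib3 and Slc7a11 fell, Aldh1l2 by 1.78 ± 0.24. In Oct4, Fras1 rose by 1.81 ± 0.29 (adjusted p = 0.0273) with As3mt and Glipr1, and Dnaaf6, Ddit3 and Slc16a3 fell. In Jhdm1b, Lum rose by 2.64 ± 0.45 (adjusted p = 0.00346) with Hmgn5 and Cxcl5, and Slc7a3 fell by 2.50 ± 0.17 (adjusted p = 2.13e-06) with Aldh1l2 and Trib3. In Oct4+Jhdm1b, Glipr1, Sncg and As3mt rose and Trib3, Aldh1l2 and C1qtnf3 fell, the last by 1.18 ± 0.22. In Oct4+Jhdm1b(jmjc), Penk, As3mt and 6030498E09Rik rose and Aldh1l2, Trib3 and Asns fell, Aldh1l2 by 1.65 ± 0.24. Penk rose by 1.96 ± 0.39 (adjusted p = 0.0378) in that infection. Without both of its arrays numbered 2, which had lower Pou5f1, As3mt still passed and the other 5 did not (adjusted p = 0.863 for Penk, 0.108 for 6030498E09Rik, 0.254 for Aldh1l2, 0.104 for Trib3 and 0.349 for Asns). The log2 change went from 1.96 to 1.08 for Penk and from -1.27 to -0.74 for Asns, but only from 1.42 to 1.29 for 6030498E09Rik, from -1.65 to -1.25 for Aldh1l2 and from -1.58 to -1.21 for Trib3. That fit sets 1 array against 1, so the lost calls do not show that the arrays numbered 2 carried these changes. Mitosis genes had medians of 0.62 in GFP, 0.66 in Oct4, 1.07 in Jhdm1b, 0.87 in Oct4+Jhdm1b and 0.67 in Oct4+Jhdm1b(jmjc). Over all genes 6, 5, 28, 19 and 9 of the 29 mitosis genes rose in that order, and 26, 26, 29, 29 and 28 adjusted over the list alone, and the list passed with an estimated correlation in each (adjusted p = 0.0054, 0.00467, 0.00626, 0.0028 and 0.0105). Cholesterol synthesis genes rose in 15 of 19 in Jhdm1b, with a median of 0.68 (adjusted p = 0.00827 with an estimated correlation), and by limma in 0 of 19 in GFP, but in 13 adjusted over the list alone, with a median of 0.39 (adjusted p = 0.012 with an estimated correlation). In Oct4 their median was 0.07, and 0 of 19 passed either way (camera adjusted p = 0.261; adjusted p = 0.767 with an estimated correlation). In Oct4+Jhdm1b and Oct4+Jhdm1b(jmjc) the medians were 0.24 and 0.32, with 0 of 19 past limma's threshold and 0 and 8 adjusted over the list alone. Those list calls (adjusted p = 1.42e-06 and 1.79e-08) were lost at adjusted p = 0.115 and 0.0574 with an estimated correlation, and the first was lost at adjusted p = 0.187, with a median of 0.11, without the Oct4+Jhdm1b array numbered 2 with vitamin C. Without the array numbered 1 of that group this median was 0.39. The p53 targets did not pass camera in Jhdm1b (adjusted p = 0.0732).

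The number of genes past the threshold differed widely between infections. A fit without 1 array leaves 1 array in its group and loses precision. A lower count in such a fit therefore does not show dependence on a particular array. In GFP 55 genes passed, 33 higher and 22 lower, with 1730 at an unadjusted p under 0.05, and leaving out any 1 of its 4 arrays left 0 to 10. In Oct4 29 passed, 23 higher and 6 lower (1562 unadjusted), with 1 to 3 without any 1 array. In Jhdm1b 792 passed, 494 higher and 298 lower (4109 unadjusted), with 178 to 606 without 1 array. In Oct4+Jhdm1b 129 passed, 97 higher and 32 lower (1968 unadjusted), with 4 to 54 without 1 array. In Oct4+Jhdm1b(jmjc) 75 passed, 53 higher and 22 lower (2067 unadjusted), with 3 to 147 without 1 array, the 147 without the array numbered 1 with vitamin C. Both arrays numbered 2 of that infection had lower Pou5f1, and without both of them 5 genes passed. Of the genes that passed in Jhdm1b, 27 higher and 18 lower genes also passed in GFP. If the calls were independent 0.818 and 0.329 would be shared. They are not fully independent, since both use the same pooled spread of each gene.

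The differences between these effects were tested as interactions. Slc7a3, for a cationic amino acid transporter, was the 1 gene past the threshold for a different vitamin C effect in Jhdm1b and in GFP, by -1.83 ± 0.24 (n = 2 per group, limma adjusted p = 0.0204). Slc7a3 was 6.66 ± 0.07 log2 (SD) in Jhdm1b without vitamin C and 4.16 ± 0.08 with it, against 5.10 ± 0.07 and 4.43 ± 0.03 in GFP. Both levels with vitamin C lay below the array medians, so a floor may limit the falls, and the groups differed mainly without vitamin C. That single gene passed limma's test, with 1403 at an unadjusted p under 0.05. Its call was lost whichever array was left out, but such a fit leaves 1 array in a group and loses precision. Mitosis genes rose more in Jhdm1b than in GFP by a median of 0.45 (camera adjusted p = 1.04e-14), as did cholesterol synthesis genes by 0.28 (adjusted p = 5.7e-06). Both calls were lost with an estimated correlation (adjusted p = 0.266 and 0.267). For Jhdm1b added to Oct4, and for Jhdm1b(jmjc) in place of Jhdm1b, 0 genes passed limma's test, with 547 and 745 at an unadjusted p under 0.05.

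Jhdm1b against GFP asked what the demethylase virus did in the absence of Oct4 virus. Interferon response genes had negative list medians in both vitamin C states, with 7 and 5 of 25 past the threshold, and the imprinted gene Peg10 rose next to the delivered gene. The list call held with an estimated correlation with vitamin C (adjusted p = 0.0212) but not without it (adjusted p = 0.0508). With vitamin C, Kdm2b rose (adjusted p = 2.23e-09) and Peg10 rose by 2.16 ± 0.34 (n = 2 against 2, limma adjusted p = 0.0108). Tmem243 rose by 1.50 ± 0.21, Nup62cl by 1.35 ± 0.24, Grik2 by 1.29 ± 0.16 and Ldoc1 by 1.27 ± 0.20, followed by Gprc5c, Neto2, Rdh10 and Apol7c. The platelet chemokine gene Ppbp fell by 2.57 ± 0.23 (adjusted p = 5.91e-05), and of interferon-induced genes Ifit1 fell by 1.76 ± 0.20 (adjusted p = 0.00085), Bst2 by 1.42 ± 0.22, Gbp3 by 1.22 ± 0.24 and Ube2l6 by 1.10 ± 0.22. Usp18, Phf11d and Cavin2 also fell. Ifit3 and Ifit3b, at -1.89 ± 0.29 and -1.93 ± 0.32, are near-identical copies and cannot be told apart with certainty. Without vitamin C Peg10 rose by 2.18 ± 0.34 (adjusted p = 0.00799) and Slc7a3 by 1.56 ± 0.17 (adjusted p = 0.000354), and Ifit3, Ifit3b and Ppbp were lower at -2.22 ± 0.29, -2.10 ± 0.32 and -2.01 ± 0.23. Of 6 CDK inhibitors Cdkn1c rose, by 0.73 ± 0.14 with (adjusted p = 0.0352) and 0.86 ± 0.14 without vitamin C (adjusted p = 0.0111). Cdkn2a at 0.12 ± 0.20 and 0.14 ± 0.20 (adjusted p = 0.884 and 0.845) and Cdkn2b at -0.11 and -0.06 did not pass.

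Of 25 interferon response genes 7 fell with vitamin C, and 22 adjusted over the list alone, with a median of -0.89 (camera adjusted p = 2.07e-31; adjusted p = 0.0212 with an estimated correlation). Without vitamin C 5 fell, and 17 adjusted over the list alone, with a median of -0.73 (adjusted p = 4.91e-24), a call lost at adjusted p = 0.0508 with an estimated correlation. Senescence-associated secretory genes had a median of -0.35 with vitamin C (adjusted p = 7.84e-05; adjusted p = 0.0212 with an estimated correlation), and 2 of 25 fell, Ereg at -1.03 ± 0.20 and Ccl5 at -0.83 ± 0.16. Without vitamin C Igfbp3 rose by 1.22 ± 0.17 and Cxcl5 fell by 1.26 ± 0.18 in that list (adjusted p = 0.00621), a call lost at adjusted p = 0.0891 with an estimated correlation. No mitosis gene passed in either state, and the list's medians were 0.20 with and -0.25 without vitamin C (adjusted p = 0.383 and 0.208 with an estimated correlation). The first of these medians was 0.11 without the Jhdm1b array numbered 1 with vitamin C. The senescence-associated secretory call without vitamin C was lost at adjusted p = 0.0527 without the GFP array numbered 1 of that state. Eomes at 1.46 ± 0.15 and the desmosome gene Dsp at 1.09 ± 0.19 rose without vitamin C. With vitamin C 70 genes passed limma's test, 35 higher and 35 lower, with 2055 at an unadjusted p under 0.05. Without vitamin C 81 passed, 39 higher and 42 lower, with 2227. Both comparisons shared 12 higher genes, among them the delivered gene Kdm2b, and 17 lower genes. If the calls were independent 0.0685 and 0.0737 would be shared. They are not fully independent, since both use the same pooled spread of each gene. Leaving out any 1 array left 5 to 10 genes with and 17 to 35 without vitamin C.

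**Figure D4:**
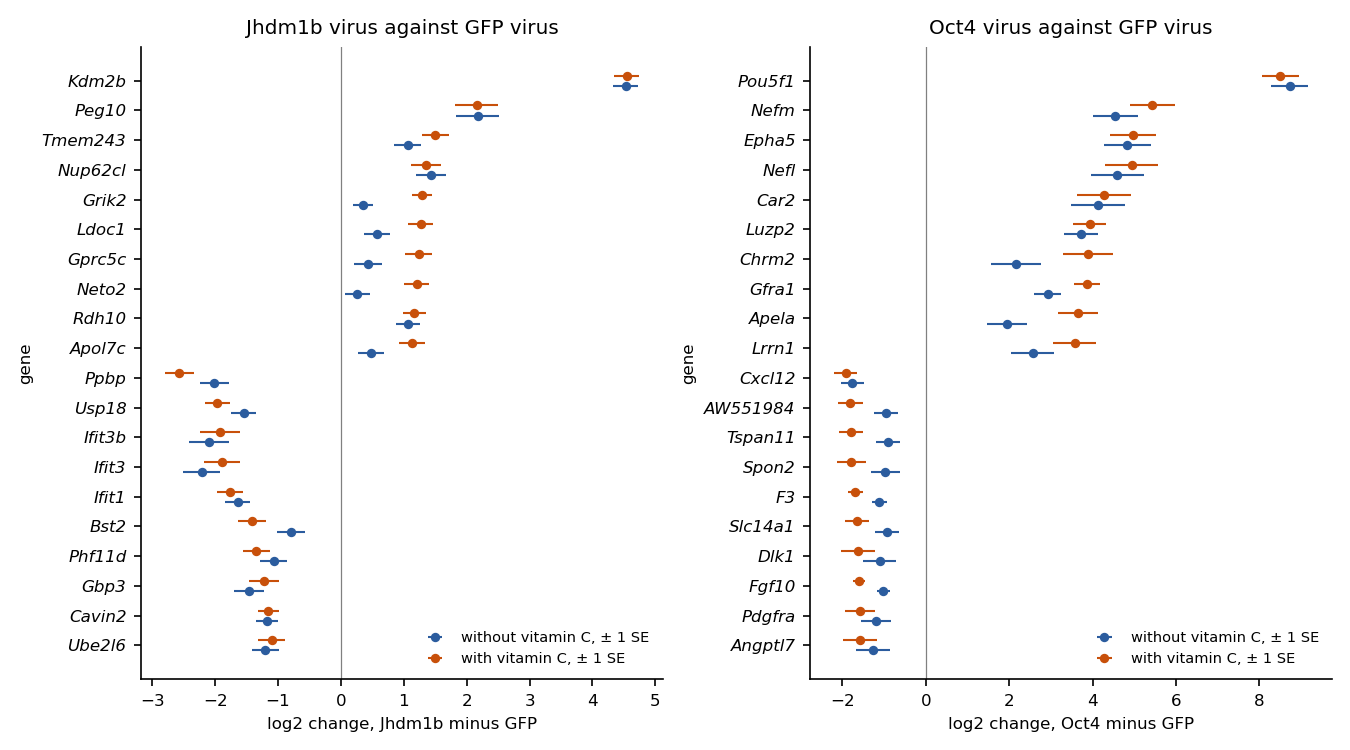
Log2 change against GFP (horizontal axis) of the genes named for Jhdm1b and for Oct4 with vitamin C (vertical axes), with points for the estimate and bars for ± 1 SE, in orange with and in blue without vitamin C, n = 2 against 2. Every gene has the same sign in both states; Kdm2b reaches 4.53 and Pou5f1 reaches 8.73 without vitamin C.

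Oct4 against GFP asked what the transcription factor did alone. With vitamin C Pou5f1 rose by 8.50 ± 0.45 (n = 2 against 2, limma adjusted p = 4.94e-08). Its GFP level was taken as background, so this is a difference from that level. The neurofilament genes Nefm and Nefl rose by 5.43 ± 0.54 (adjusted p = 5.5e-05), a 43.1-fold increase, and 4.94 ± 0.64. Epha5 rose by 4.97 ± 0.56, Car2 by 4.27 ± 0.65, Luzp2 by 3.93 ± 0.41, Chrm2 by 3.90 ± 0.60, Gfra1 by 3.87 ± 0.32, Apela by 3.66 ± 0.48 and Lrrn1 by 3.57 ± 0.52. The chemokine gene Cxcl12 fell by 1.92 ± 0.28 (adjusted p = 0.000827), and AW551984, Tspan11, Spon2, F3, Slc14a1, Dlk1, Fgf10, Pdgfra and Angptl7 fell as well, Fgf10 by 1.59 ± 0.15. Without vitamin C Pou5f1 rose by 8.73 ± 0.45, Epha5 by 4.84 ± 0.56 and Nefl by 4.60 ± 0.64, and Cxcl12, Gjb2 and Itih2 were lower at -1.76 ± 0.28, -1.61 ± 0.26 and -1.35 ± 0.16. Of 30 pluripotency genes Nr0b1 and Gdf3 rose with vitamin C, by 1.50 ± 0.32 and 0.63 ± 0.15, and Nr0b1 rose without it, by 1.56 ± 0.32. None of 5 hairpins of the miR-302 cluster passed in either state.

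Among 15 neural and glial markers 3 rose with vitamin C, Map2 by 1.94 ± 0.26, S100b by 1.54 ± 0.25 and Elavl4 by 1.41 ± 0.30, and the list did not pass camera (adjusted p = 0.133). Senescence-associated secretory genes went both ways, with 5 of 25 higher, such as Ccl8 at 2.39 ± 0.37 and Il6 at 1.88 ± 0.33, and 3 lower, such as Igfbp5 at -1.13 ± 0.24 (adjusted p = 0.325). Mesenchymal genes also went both ways, with 3 higher, such as Postn at 2.70 ± 0.38, and 3 lower, such as Pdgfra. Cholesterol synthesis genes had a median of -0.32, and 7 fell adjusted over the list alone (adjusted p = 0.00044), a call lost at adjusted p = 0.546 with an estimated correlation. Without vitamin C 12 of 25 interferon response genes rose, and 19 adjusted over the list alone, such as Ifit1 at 1.40 ± 0.20 and Usp18 at 1.18 ± 0.20 (adjusted p = 7.63e-17), a call lost at adjusted p = 0.284 with an estimated correlation. Acta1 at -1.17 ± 0.19 and Des at -0.87 ± 0.19 fell among 22 muscle markers (adjusted p = 0.00219; adjusted p = 0.323 with an estimated correlation). With vitamin C 782 genes passed limma's test, 521 higher and 261 lower (3005 unadjusted), and without it 851, 617 higher and 234 lower (3571 unadjusted). Both states shared 343 higher and 96 lower genes, where 16.1 and 3.06 would be shared if the calls were independent. Here too both use the same pooled spread of each gene. Without any 1 array the counts lay between 247 and 550 with and between 253 and 408 without vitamin C.

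Oct4+Jhdm1b against Oct4 asked what Jhdm1b added to Oct4, and Kdm2b alone passed the threshold. With vitamin C 10% of simulated changes of 0.5 log2 were recovered in this comparison, so changes of that size were mostly out of reach. Kdm2b rose by 3.57 ± 0.19 with vitamin C (n = 2 against 2, limma adjusted p = 8.82e-08) and by 3.86 ± 0.19 without it (adjusted p = 2.73e-08). Pou5f1 differed by -0.65 ± 0.45 and -0.41 ± 0.45 (adjusted p = 0.916 and 0.953). These SEs use a spread pooled over all 10 groups. Oct4+Jhdm1b(jmjc), outside this comparison, had the widest, with SDs of 1.2 and 0.92. Over 342 genes chosen because they rose with Oct4, the Oct4+Jhdm1b arrays reached 76.6% to 87.8% of the Oct4 response. The genes were chosen in the Oct4 arrays, which also define the response, so selection alone can put other arrays below it. Selection, a lower level of Oct4 and the added Jhdm1b could therefore not be told apart here. Kdm2b was the 1 gene past the threshold in both states, with 1141 and 1238 genes at an unadjusted p under 0.05. Leaving out 1 array gave 1 to 11 genes with and 1 to 2 without vitamin C. Cdkn1c, which rose with Jhdm1b alone, was at 0.62 ± 0.14 with vitamin C (adjusted p = 0.327). Of the genes called for Jhdm1b against GFP with vitamin C, 30 of 35 higher and 33 of 35 lower ones had the same sign on Oct4, and without vitamin C 37 of 39 and 40 of 42. Interferon response genes had medians of -0.12 with (adjusted p = 0.0383) and -0.19 without vitamin C (adjusted p = 0.00275), with 0 of 25 members past the threshold. Both calls were lost with an estimated correlation (adjusted p = 0.695 and 0.728), and each in 2 of 4 fits without an array, up to adjusted p = 0.603 and 0.0935 without the Oct4 array numbered 2 of that state. With vitamin C the interferon median was -0.06 without that array and -0.22 without the Oct4 array numbered 1. Senescence-associated secretory genes had a median of -0.23 with vitamin C (adjusted p = 0.00467), lost at adjusted p = 0.106 with an estimated correlation. By camera 7 and 5 lists passed with and without vitamin C, and 0 with an estimated correlation.

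The jmjc virus was set against Jhdm1b on the Oct4 background and against Oct4 alone. Kdm2b differed between Oct4+Jhdm1b and Oct4+Jhdm1b(jmjc) by 0.11 ± 0.19 with and 0.06 ± 0.19 without vitamin C (adjusted p = 0.907 and 0.999), and Pou5f1 by 0.65 ± 0.45 and 0.64 ± 0.45 (adjusted p = 0.726 and 0.999). In this comparison 0 genes passed limma's test in either state, with 1589 and 949 at an unadjusted p under 0.05 and smallest adjusted p of 0.6 and 0.204. Cdkn2a was at -0.59 ± 0.20 with vitamin C (adjusted p = 0.6). Mitosis genes were higher with Jhdm1b than with jmjc by a median of 0.25 with vitamin C (camera adjusted p = 4.74e-12) and DNA replication genes by 0.21 (adjusted p = 1.06e-08), and both calls were lost at adjusted p = 0.297 with an estimated correlation. Without the jmjc array numbered 2 with vitamin C, which had lower Pou5f1, the medians were 0.17 and 0.09, and the DNA replication call was lost (adjusted p = 0.0633). The DNA replication median was 0.37 without the jmjc array numbered 1, and the mitosis median 0.39 without the Oct4+Jhdm1b array numbered 1. Against Oct4, Kdm2b rose with the jmjc virus by 3.46 ± 0.19 with vitamin C (adjusted p = 1.41e-07) and by 3.80 ± 0.19 without it (adjusted p = 3.41e-08), the 1 gene past the threshold in each state, with 2353 and 1492 at an unadjusted p under 0.05. Pou5f1 was at -1.30 ± 0.45 and -1.05 ± 0.45 (adjusted p = 0.287 and 0.605). Interferon response genes had a median of -0.48 without vitamin C (adjusted p = 1.18e-11), and 5 fell adjusted over the list alone, a call lost at adjusted p = 0.351 with an estimated correlation. Without the Oct4+Jhdm1b(jmjc) array numbered 2 of that state, which had lower Pou5f1, the interferon median was -0.17 (adjusted p = 0.0215). These counts moved with the Oct4+Jhdm1b(jmjc) arrays: without the array numbered 1 with vitamin C, the one with higher Pou5f1, 654 genes passed against Oct4 and 45 against Oct4+Jhdm1b. Without the array numbered 1 without vitamin C 50 genes passed against Oct4 and 0 against Oct4+Jhdm1b.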

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

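The tests of the interferon genes against the GFP cultures and against Oct4+Jhdm1b, of the amino acid genes under scaling, and of the Pou5f1 arrays were chosen after the result was seen, as was leaving out arrays from the interaction lists. The tests for a single deviating array among the interferon arrays and for splits of the arrays were written down before their results were seen. The ATF4 and chaperone tests were also written down beforehand, on gene lists made after the data had been examined.

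Interactions asked whether the effect of vitamin C differed between infections. The list calls were lost with an estimated correlation, and several also when an array was left out. Slc7a3 fell by 1.83 more in Jhdm1b than in GFP (limma adjusted p = 0.0204). This call was lost whichever array was left out, though such a fit leaves 1 array in a group and loses precision. A floor may limit the Slc7a3 difference, since its levels with vitamin C lay below the array medians in both infections. Between Jhdm1b and GFP the vitamin C effect differed by a median of 0.445 for mitosis, 0.171 for DNA replication and 0.284 for cholesterol synthesis genes (camera adjusted p = 1.04e-14, 0.0016 and 5.7e-06), calls lost with an estimated correlation (adjusted p = 0.266, 0.492 and 0.267). With an array left out these medians ranged from 0.381 to 0.581, 0.133 to 0.263 and 0.251 to 0.318, and the DNA replication call was lost without the Jhdm1b array numbered 1 with vitamin C (adjusted p = 0.139). Between Oct4+Jhdm1b and Oct4 the medians were 0.216, 0.161 and 0.173 for the same lists (adjusted p = 4.52e-05, 0.00175 and 0.00175), again lost with an estimated correlation (adjusted p = 0.566, 0.644 and 0.566). With an array left out they ranged from 0.118 to 0.332, 0.0765 to 0.281 and 0.0611 to 0.314, the lowest each without an Oct4+Jhdm1b array numbered 2, where adjusted p reached 0.214, 0.265 and 0.797. Between Oct4+Jhdm1b and Oct4+Jhdm1b(jmjc) they were 0.196 for mitosis, 0.133 for ribosome biogenesis and -0.371 for interferon response genes (adjusted p = 2.61e-04, 0.00865 and 2.56e-07), lost in the same way (adjusted p = 0.561, 0.718 and 0.478). With an array left out they ranged from 0.0485 to 0.282, -0.0008 to 0.235 and -0.591 to -0.141, the values nearest 0 each without an Oct4+Jhdm1b(jmjc) array numbered 2, where adjusted p reached 0.313, 0.79 and 0.186. Groups of 2 arrays are too small for a search for single deviating arrays.

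The Oct4+Jhdm1b(jmjc) arrays numbered 2 differed in Pou5f1 from the arrays numbered 1 by -1.70 and -1.30 log2 with and without vitamin C. Dilution with uninfected cells was argued against by Kdm2b, which did not fall with Pou5f1 but was higher by 0.439 on average, where its differences in the 4 other pairs with Jhdm1b virus lay between -0.0433 and 0.171. An array from an infection without Oct4 was argued against as well, since the lower Pou5f1 value lay 6.07 above the highest of the 8 arrays without Oct4 virus. A lower dose of Oct4 in those cultures stays a candidate explanation: 438 genes that changed with Oct4 in both states moved back by a median of -0.396 and -0.419, against -0.134 to -0.0296 in the other 4 pairs with Oct4 virus. Over the 342 of these genes that rose with Oct4, those arrays reached 39.8% and 38.5% of the Oct4 response and the arrays numbered 1 reached 78.8% and 78.6%. The Oct4+Jhdm1b arrays reached 76.6% to 87.8%, so the jmjc arrays numbered 1 lay within their range. The Oct4 arrays, in which these genes were chosen and which define the response, reached 92.7% to 107%. Selection alone can put the other arrays lower than these.

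Interferon response genes had list medians of -0.889 with and -0.729 without vitamin C for Jhdm1b against GFP, with 7 and 5 of 25 past the threshold. With an estimated correlation the list passed with vitamin C (adjusted p = 0.0212) but not without it (adjusted p = 0.0508). Whether the GFP cultures were raised on their own could not be decided. The lower Oct4 array lay above the higher Jhdm1b array by at least 0.891 in list median in both vitamin C states. Oct4 arrays are no neutral reference, however, as the list median was 0.689 for Oct4 against GFP without vitamin C. A single deviating array was argued against, as the list median stayed between -0.981 and -0.592 in 8 fits that each left out an array. Cultures that differed for reasons other than Jhdm1b may still be the source: adding Jhdm1b to Oct4 changed the list by -0.116 at the higher of the 2 medians, far less than against GFP, and with 2 arrays per group a culture difference and an effect of Jhdm1b alone cannot be told apart. Kdm2b was also lower in Oct4+Jhdm1b, at 9.57 with and 9.77 without vitamin C, than in Jhdm1b, at 10.36 and 10.40. An effect of Jhdm1b that needs the absence of Oct4, or the higher level of Kdm2b, was not tested.

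Amino acid stress genes were lower with vitamin C, among them Aldh1l2, Trib3, Asns and Ddit3. A list of 29 measured ATF4 amino acid response genes had a median of -0.69, but it held the genes that drew attention and so gives no test. The 11 aminoacyl-tRNA synthetase genes all fell, with a median of -0.472 (unadjusted camera p = 0.0105 with an estimated correlation). A remaining difference in array level was too small to explain the fall of the 29 genes. Centring each array moved the median of all genes by 0.015 and left the list at -0.675. How RMA had scaled the arrays could not be examined. A lower ATF4 programme is a candidate explanation, as the 17 list members other than those that drew attention had a median of -0.424 and 16 of them fell (unadjusted camera p = 0.00353 with an estimated correlation). Lower stress of the endoplasmic reticulum stays open: its 18 chaperones had a median of -0.0956, with 5 lower, which is closer to the bound set at -0.1 than the SD of 0.0862 between infections. Their unadjusted camera p was 0.0013, and 0.0557 with an estimated correlation. The chaperone median was 0.0181 in Jhdm1b, where the ATF4 list fell most, at -0.844, and below 0 in the other infections. No other biological explanation was tested.

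Splits of the arrays within each infection argued against chance for the number of genes called for the average vitamin C effect. This holds only if the 2 arrays of a group are separate samples, which the labels do not state. It also assumes that equally numbered arrays are not linked. The real grouping gave 1989 genes and the highest of the others gave 952, so that 1 of 100 splits, the real one, gave as many. If each group is a single culture, only whole groups can be exchanged, and the 16 such splits are too few for a share under 0.05: the real value was 1989 and the highest other 652.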

How the results depend on the processing

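Leaving out both Oct4+Jhdm1b(jmjc) arrays numbered 2, leaving out the Jhdm1b infection from the average, and leaving out each array from the list tests were chosen after the data were seen, and the other alternatives before. The average vitamin C effect stayed within 1.5 times of 1989 genes under all alternatives but the added fold threshold. Centring on array medians and repeated quantile normalization moved the median of all genes by at most 0.0556 log2. Where no reason is given, the cause was not tested.

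A required change of at least 1 log2 left, by its construction, 21 genes for the average vitamin C effect, 21 in GFP, 11 in Oct4, 148 in Jhdm1b, 29 in Oct4+Jhdm1b and 20 in Oct4+Jhdm1b(jmjc). It left 28 and 39 for Jhdm1b against GFP with and without vitamin C, and 322 and 279 for Oct4 against GFP. A variance prior with trend and robust fitting gave 143 genes for vitamin C in GFP, 105 in Oct4, 226 in Oct4+Jhdm1b and 190 in Oct4+Jhdm1b(jmjc), 144 and 167 for Jhdm1b against GFP with and without vitamin C, 5 and 9 for Oct4+Jhdm1b against Oct4, and 1 for Oct4+Jhdm1b against Oct4+Jhdm1b(jmjc) without vitamin C. Array quality weights gave 140 for vitamin C in GFP, 52 in Oct4 and 39 in Oct4+Jhdm1b(jmjc), and 129 for Jhdm1b against GFP with vitamin C.

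Genes at or above the median mean level, of which fewer were tested, gave 139 for vitamin C in GFP, 119 in Oct4, 273 in Oct4+Jhdm1b and 209 in Oct4+Jhdm1b(jmjc), 153 and 170 for Jhdm1b against GFP, 2 and 5 for Oct4+Jhdm1b against Oct4, and 0 for the interaction of vitamin C and Jhdm1b by limma, since Slc7a3 was not among the genes tested there. Fits of the compared groups alone, with fewer samples, gave 2 for vitamin C in GFP, 1 in Oct4, 227 in Jhdm1b, 0 in Oct4+Jhdm1b and 0 in Oct4+Jhdm1b(jmjc) by limma, and 11 and 11 for Jhdm1b against GFP. Centring on array medians gave 19 for vitamin C in Oct4, repeated quantile normalization gave 115 in Oct4+Jhdm1b(jmjc), and all probe sets gave 48 in Oct4 and 2 for Oct4+Jhdm1b(jmjc) against Oct4 with vitamin C. With centring the share of higher genes went from 62.4% to 74.8% for vitamin C in Jhdm1b and from 48.1% to 38.1% for Jhdm1b against GFP without vitamin C.

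The labels give the groups the same replicate numbers without saying that equal numbers share a culture or day. Across 45 pairs of groups the deviations of equally numbered arrays correlated from -0.173 to 0.30, with a median of 0.0544, and above 0.1 in 16. The arrays were not paired because not every pair exceeded 0.1, a strict rule that a shared culture or day need not meet. Pou5f1 was lower on the array numbered 2 in all 6 pairs with Oct4 virus, by values from -1.70 to -0.337. On the first principal component the array numbered 2 lay lower in every group but Oct4+Jhdm1b with vitamin C. A link between equal numbers therefore stays open, also in groups without Oct4 virus. A block for that number gave 66 genes for vitamin C in Oct4 and 126 in Oct4+Jhdm1b(jmjc), 3 and 3 for Oct4+Jhdm1b against Oct4 with and without vitamin C, and 3 for Oct4+Jhdm1b(jmjc) against Oct4 with vitamin C. The block left all 107 named genes and all 118 list calls past the threshold.

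With 1 array left out at a time, and the lone array assumed to vary like the other groups, the counts ranged from 1669 to 2063 for the average vitamin C effect, 0 to 10 in GFP, 1 to 3 in Oct4, 178 to 606 in Jhdm1b, 4 to 54 in Oct4+Jhdm1b and 3 to 147 in Oct4+Jhdm1b(jmjc). With and without vitamin C they ranged from 5 to 10 and 17 to 35 for Jhdm1b against GFP, 247 to 550 and 253 to 408 for Oct4 against GFP, 1 to 11 and 1 to 2 for Oct4+Jhdm1b against Oct4, 0 to 45 and 0 to 0 for Oct4+Jhdm1b against Oct4+Jhdm1b(jmjc), and 1 to 654 and 1 to 50 for Oct4+Jhdm1b(jmjc) against Oct4. The interactions gave 0 in every such fit by limma.

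Leaving out both Oct4+Jhdm1b(jmjc) arrays numbered 2 gave 5 genes for vitamin C in that infection and reversed 4 list tests, none of which then passed: ribosome biogenesis and interferon response for vitamin C in Oct4+Jhdm1b(jmjc) (adjusted p = 0.179 and 0.342), interferon response for Oct4+Jhdm1b against Oct4+Jhdm1b(jmjc) without vitamin C (adjusted p = 0.619), and ribosome biogenesis in the jmjc interaction (adjusted p = 0.657). With 1 array left out at a time 126 of 636 list tests were lost and 5 reversed, though none of those reversed passed. Over such fits the adjusted p of those reversed lists ranged from 0.000752 to 0.86 for ribosome biogenesis and from 5.09e-12 to 0.757 for interferon response for vitamin C in Oct4+Jhdm1b(jmjc), from 0.000236 to 0.961 for mitosis in Oct4+Jhdm1b against Oct4 with vitamin C, and, for Oct4+Jhdm1b against Oct4+Jhdm1b(jmjc), from 6.83e-07 to 0.956 for collagens with and from 4.4e-15 to 0.637 for interferon response without vitamin C.

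Named genes kept their direction under every alternative in which they were tested. The call was lost in 34 of 87 tests with the compared groups alone, in 143 of 752 with 1 array left out, in 5 of 28 without the Oct4+Jhdm1b(jmjc) arrays numbered 2, in 3 of 107 with trend and robust fitting, and in 1 of 107 each with array weights, repeated quantile normalization and all probe sets. With trend and robust fitting these were Penk for vitamin C in Oct4+Jhdm1b(jmjc) (adjusted p = 0.0845), and Dlk1 and Angptl7 for Oct4 against GFP with vitamin C (both adjusted p = 0.0812). Penk was also lost with array weights (adjusted p = 0.105), and Angptl7 with repeated quantile normalization (adjusted p = 0.0592) and all probe sets (adjusted p = 0.0631). Of list calls, 91 of 118 were lost with an estimated correlation, 74 of 118 with fry and 30 of 114 among genes at or above the median mean level. Signal over background may limit dim genes, though background was not measured: Pou5f1 read from 3.49 to 3.85 log2 in groups without Oct4 virus, so genes near that level may carry little signal.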
